A study of Mus musculus with 2 samples.

How the data were processed

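Ovarian cells of female ICR mice were profiled by single-cell RNA sequencing with BD Rhapsody bead capture and Illumina sequencing, per the labels' protocols. Gavage began at 3 weeks of age and was given daily for 35 days, and the ovaries were taken at 8 weeks. The control library came from mice given water (ddH2O). The PS-MP library came from mice given 1 mg of polystyrene microplastics of 0.1 µm in 100 µL per day. The labels state n = 16 mice without saying whether this number holds per group or for both groups together. No label or file ties a cell to a mouse, so each group was treated as 1 sample.

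The authors deposited raw molecule counts (UMI counts) per gene and cell, as whole numbers of at least 1 with no normalization. The submitters' processing notes name the genome build GRCm39 and Seurat without giving their role. The aligner, the tool that counted molecules, the cell calling and the annotation release are not given in the sources used here. Cell types were rebuilt here, since no cell type annotation was used. The lowest total per cell was 3738 counts in the control library and 3575 in the PS-MP library, so shallower cells were absent from the deposited files. The gene files listed 28214 and 27708 symbols, of which 26549 were in both; a gene absent from a file was set to 0. Genes were identified by symbol alone and no coordinates were used.

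Cells with at least 500 detected genes and at most 25% mitochondrial counts were retained. In the control library 1 cell failed the first limit and 520 failed the second; in the PS-MP library these numbers were 0 and 286. Doublets were called per library with scrublet as run by scanpy 1.11.5, with an expected rate of 0.05, and were left out. The caller marked 315 control cells (2.12%) and 358 PS-MP cells (2.42%). Counts per cell were scaled to 10000 and logged, and 2000 variable genes were chosen across the libraries. Both libraries were clustered together from 30 principal components and 15 neighbours with the Leiden method (leidenalg 0.10.2) at resolution 0.5. No batch correction was applied, because with 1 library per group it would also remove differences between the groups. The seed was 1 throughout.

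Clusters were named only from marker lists fixed before the data were examined, as were the filters, the gene lists, the rule for named genes and most alternative settings. A cluster took the class whose markers had the highest mean relative level (CPM of the cluster over that of the highest cluster, with 5 CPM added below). At least 3 of the markers had to reach 20 CPM and the mean had to reach 0.15; this scoring was set after the files were read. Names are given as "-like" because they rest on these markers and not on the study's own annotation. No cluster was named from the lymphatic endothelial, oviduct or other epithelium, neutrophil, B, mast, erythroid, glia or adipocyte markers.

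Shares of cells were given with exact Clopper-Pearson binomial intervals at 95%. For expression, raw counts were summed per class and library and scaled to that class's total as CPM. The PS-MP over control ratio of CPM values was given with its exact conditional binomial interval at 95%. All intervals cover counting error only and not differences between animals or preparations. A gene entered a count when its CPM was at least 20 in a library and its ratio was at least 1.5 in either direction. This was done for granulosa-like cells, for each other class with at least 200 cells in both libraries, and for all cells summed. These counts describe size and are not tests.

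The 31 gene lists were summarised by the median log2 ratio of their members with at least 20 CPM in a library, after adding 1 CPM to both values. Members at least 1.2-fold higher, at least 1.2-fold lower and in between were counted. Each median was placed as a percentile among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. The percentile describes these 2 libraries and is not a test of the exposure. A percentile of 100 means that every random list had a lower median.

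Genes were named by a fixed rule. A gene was eligible with at least 50 CPM in a library and with a CPM at least 0.1 times that in every other class. Ribosomal protein, mitochondrial, haemoglobin and unnamed gene models were not eligible. The 10 highest and 10 lowest ratios were named in granulosa-like cells, and the 3 highest and 3 lowest in each other class. Up to 4 members per gene list with the largest ratios, and the cell type markers, could be named in addition. Genes named outside this rule were chosen after their values were seen: Igfbp4, the leading genes of cluster 17, Top2a and Mki67, the members in the plot of the interferon list and the genes used to gauge carried-over RNA. Of the gene lists 1, and of the named genes 1 in blood endothelial-like cells, are not reported here.

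Granulosa-like cells were clustered again at resolution 0.5, with 0.3 and 0.8 as alternatives. Sub-clusters were compared in size only where none of their 10 leading genes with at least 20 CPM differed 1.5-fold between the libraries in the whole class. This reading of the fixed rule was set after the sizes were seen. For 2 sub-clusters outside this rule the shares are given as values, with the genes that put them outside it. Where shares of cells with a UMI were compared, each cell was thinned to 3500 UMIs, which was below the shallowest cell, so 0 cells were left out.

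Alternatives that were planned covered doublets, a stricter cell filter (1000 genes, 15% mitochondrial counts), Leiden resolution 1, libraries clustered apart, cell cycle genes left out of the variable genes, and scaling by the median of ratios. They also covered thinned cells, the mean of each cell's own CPM, sub-clusters weighted alike in both libraries, CPM floors of 5 and 50, a ratio of 2, and pseudocounts of 0.1 and 5 CPM. The weighting left out sub-clusters with fewer than 20 cells in a library. Alternatives chosen after seeing the data treated cluster 17, cluster 2, mixed sub-clusters and a sub-cluster led by Kcnk3 in other ways. The calculation was tested on simulated counts with 100 genes changed 3-fold and 100 changed 2-fold. These counts were drawn gene by gene with counting error alone. They hold no variation between animals or preparations and no correlation between genes. The simulation therefore checks the calculation and not how often such ratios or percentiles arise between unexposed libraries. In simulated granulosa-like cells with 7244 genes, 99 of the 3-fold and 100 of the 2-fold genes were found and 0 other genes passed. In simulated blood endothelial-like cells with 7250 genes, 99 and 92 were found and 86 other genes passed. In simulated macrophage or monocyte-like cells with 6902 genes, 100 and 98 were found and 27 other genes passed. A list of 37 genes shifted by 0.30 on the log2 scale gave a median of 0.29 in simulated granulosa-like cells, while 0 of 29 other lists fell outside the central 95% of random lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.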

Results

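Single ovarian cells were sequenced in 2 libraries, 1 from control mice and 1 from mice given polystyrene microplastics of 0.1 µm (PS-MPs) by gavage from weaning for 35 days. The deposited files held 15373 cells with 160257194 UMI counts in the control library and 15056 cells with 145474989 UMI counts in the PS-MP library. The median was 9426 UMI counts per cell in the control library and 8613.5 in the PS-MP library. After filtering, 14538 and 14412 cells remained, with medians of 3488.5 and 3299 detected genes. The series title names granulosa cells, the cytoskeleton and epigenetic regulation, so the comparison asks how expression in granulosa-like and other ovarian cells differed between the exposed and the control library. With 1 library per group there is no replicate check and no test of the exposure: each difference compares these 2 libraries, and each interval covers counting error only.

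In the PS-MP library, granulosa-like cells carried less mRNA for several genes known from growing follicles and slightly more for chaperones of the endoplasmic reticulum. Grem1, which encodes a BMP antagonist, stood at 239.6 CPM in the control library and 63.1 CPM in the PS-MP library, a ratio of 0.263 (95% interval 0.256 to 0.271). Cyp19a1, the aromatase that makes oestrogens, had a ratio of 0.488 (0.475 to 0.501), and Inhba, a subunit of activin and inhibin, had a ratio of 0.552 (0.549 to 0.555). Interferon-response genes were higher in the PS-MP library in theca-like, stromal fibroblast-like and macrophage or monocyte-like cells, with median log2 ratios of 0.46, 0.63 and 0.70. The median in blood endothelial-like cells was 0.23. A luteal-like cluster with Lhcgr, Cyp11a1 and Edn2 mRNA held 1893 cells of the PS-MP library and 4 cells of the control library.

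Clustering gave 18 clusters, each named from fixed markers. Clusters 3, 4, 5, 6, 7, 9 and 12 were granulosa-like; cluster 0 was theca-like (led by Cyp17a1) and cluster 1 stromal fibroblast-like (Col1a1, Mfap4, Tcf21, Lum, Dcn). Blood endothelial-like cells formed cluster 8 (Cldn5, Kdr, Flt1), macrophage or monocyte-like cells cluster 10 (Lyz2, C1qa, C1qb), and smooth muscle or pericyte-like cells cluster 11 (Rgs5, Myh11, Notch3). Cluster 13 was oocyte-like (Zp2, Ooep, Dppa3), cluster 15 T or NK or innate lymphoid-like (Gzma, Nkg7, Ncr1) and cluster 16 surface epithelium-like (Upk3b, Krt19, Muc16). Cluster 14 was dendritic-like by its marker score, but its leading genes were Siglech, Ccr9 and Cox6a2, with 0 of the fixed dendritic markers among them. The granulosa-like clusters were led by mitotic genes in cluster 3 (Ccnb1, Ccna2, Cdc20), by Ntng1 and Lrrtm3 in cluster 4, by Galnt15 and Ntn4 in cluster 5, by Amh and Igfbp5 in cluster 7 and by Car4 and Omg in cluster 12. Inhba, Cyp19a1 and Grem1 were among the leading genes of both cluster 6 and cluster 9.

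**Figure D1:**
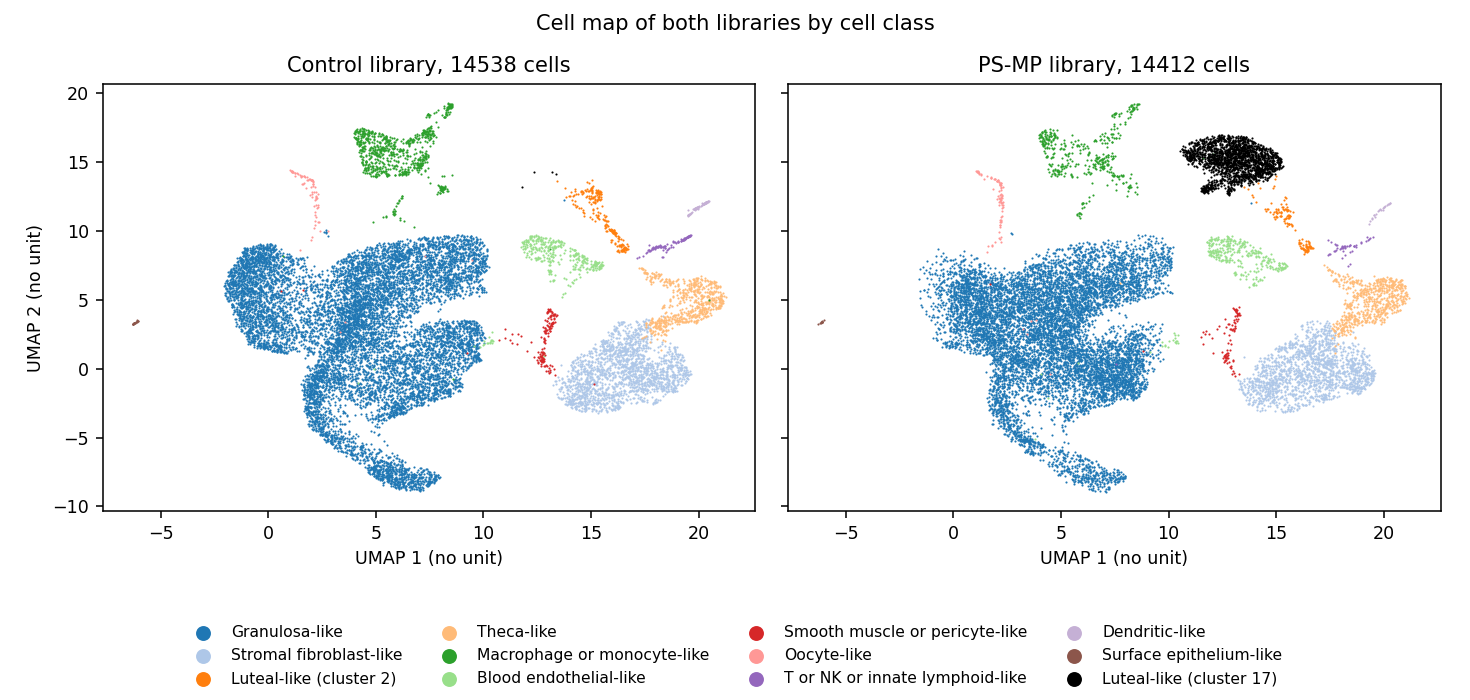
Cell map (UMAP axes, no unit) of the control library with 14538 cells and the PS-MP library with 14412 cells; each point is a cell, coloured by class, with cluster 17 in black. Cluster 17 holds 4 control cells and 1893 PS-MP cells.

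Granulosa-like cells made up 70.4% of control cells (69.7 to 71.1) and 63.3% of PS-MP cells (62.5 to 64.0). Luteal-like cells made up 1.62% (1.42 to 1.84) and 14.1% (13.5 to 14.6). The luteal-like class came from different clusters in the libraries: cluster 2 held 232 of its control cells and 134 of its PS-MP cells, and cluster 17 held 4 and 1893. A cluster held almost wholly by 1 library may belong to that library and not be a cell type. With cluster 17 left out of all cells, granulosa-like shares were 70.4% and 72.8% and luteal-like shares 1.60% and 1.07%, so both orders of the libraries turned with it. Counted as granulosa-like, it gave granulosa-like shares of 70.4% and 76.4%.

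Cluster 17 carried fixed luteal and steroidogenic markers, several of them at lower levels than in cluster 2 and several at higher levels. The cluster 2 levels given here pool its 232 control and 134 PS-MP cells, while those of cluster 17 are of PS-MP cells alone. Lhcgr, the receptor for luteinising hormone, stood at 1237 CPM in PS-MP cells of cluster 17, at 1322 CPM in cluster 2 and at 26.5 CPM in granulosa-like PS-MP cells. Cyp11a1, the side-chain cleavage enzyme of steroid synthesis, stood at 6979, 10224 and 106 CPM in that order. Ptgfr, the receptor for prostaglandin F2α, stood at 71.7 CPM in cluster 17 and 1254 CPM in cluster 2, and Akr1c18, which inactivates progesterone, at 88.7 and 2947 CPM. The order was the opposite for Parm1 at 455 and 70.9 CPM, Cited4 at 861 and 568, Mgarp at 1807 and 589, and Fdx1 at 5995 and 4022. The 10 genes that led cluster 17 were Xpnpep2, Edn2, Slc12a8, Timp4, Cplx1, Tinagl1, Sstr1, Cemip, Bhmt and Ptgs1, and 0 of them were fixed luteal markers. Its marker score was 0.593 for the luteal class and 0.118 for granulosa, the next class.

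Macrophage or monocyte-like cells made up 5.55% of control cells (5.18 to 5.94) and 2.75% of PS-MP cells (2.49 to 3.04). All immune classes together made up 6.72% (6.32 to 7.14) and 3.24% (2.96 to 3.54); without cluster 17 the shares were 6.72% and 3.73%. T or NK or innate lymphoid-like cells were 0.681% and 0.333%, and dendritic-like cells 0.488% and 0.153%. Stromal fibroblast-like cells were 12.6% and 11.4%, theca-like cells 4.53% and 4.47%, and blood endothelial-like cells 2.42% and 2.19%. Without cluster 17 the order turned for each of these 3 classes, with stromal fibroblast-like shares of 12.6% and 13.2%, theca-like shares of 4.53% and 5.15% and blood endothelial-like shares of 2.42% and 2.52%, and the intervals of each class overlapped. Smooth muscle or pericyte-like cells were 0.997% and 0.631%, oocyte-like cells 0.530% and 0.624%, and surface epithelium-like cells 0.138% and 0.083%. The intervals of theca-like, blood endothelial-like, oocyte-like and surface epithelium-like shares overlapped between the libraries. Kept cells had median depths of 9502.5 UMIs in the control library and 8643 in the PS-MP library, and the deposited files held no cell under 3575 UMIs, so shares of shallow cell types depend on that lower limit.

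**Figure D2:**
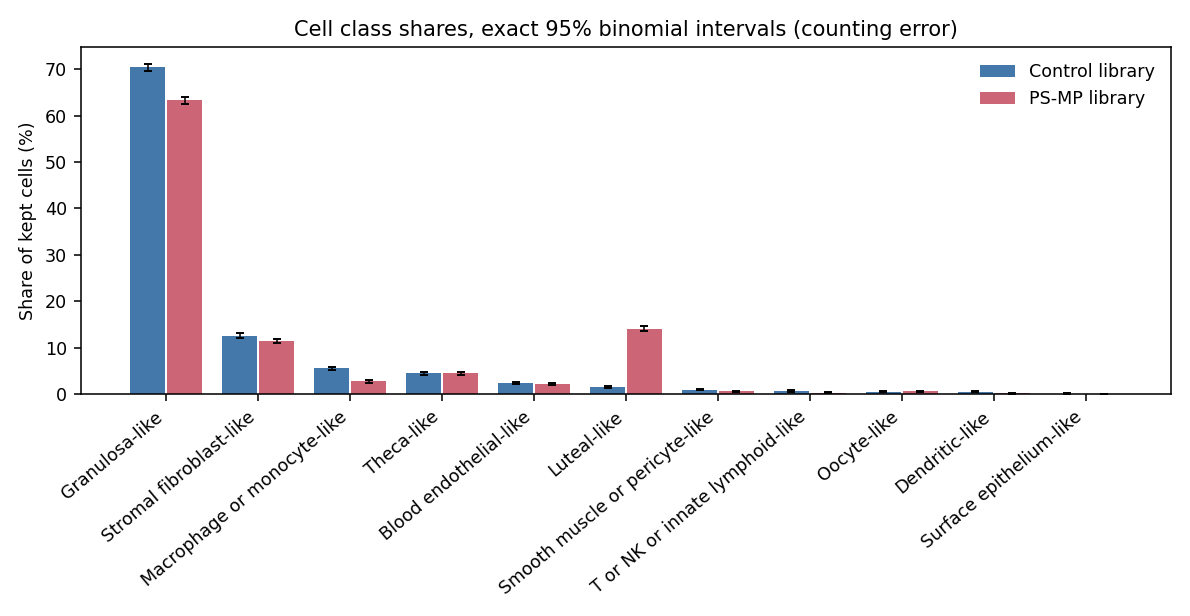
Share of kept cells (percent) in each cell class, with bars for the control library and the PS-MP library and exact 95% binomial intervals for counting error. Luteal-like cells were 1.62% and 14.1%, and macrophage or monocyte-like cells 5.55% and 2.75%.

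Of 7350 genes with at least 20 CPM in granulosa-like cells, 4 were at least 1.5-fold higher and 34 at least 1.5-fold lower in the PS-MP library. The 4 were Igfbp4, Sdf2l1, Pgbd5 and Spc24. More genes were higher in thinned cells and with sub-clusters weighted alike, as given with the processing alternatives. Cluster by cluster, the higher and lower genes numbered 63 and 125 in cluster 6 and 45 and 75 in cluster 9, but 64 and 55 in cluster 3 and 47 and 37 in cluster 5. They numbered 18 and 26 in cluster 4, 31 and 41 in cluster 7 and 89 and 95 in cluster 12. With cluster 17 counted as granulosa-like, 254 genes were higher and 98 lower. Igfbp4, which binds insulin-like growth factors, had a ratio of 2.27 (2.18 to 2.36) and stood at 72.2 CPM in granulosa-like PS-MP cells and up to 1131 CPM in blood endothelial-like cells. Among the named genes, Sdf2l1, an endoplasmic reticulum protein of the folding machinery, was highest at 1.57 (1.53 to 1.61). Pgbd5 followed at 1.54, Spc24, a kinetochore subunit, at 1.53, and Slc38a1, an amino acid transporter, at 1.48. Rgcc had a ratio of 1.45, Sh3bp5 of 1.42, Crabp2, a retinoic acid binding protein, of 1.41, Fdxr, which passes electrons to mitochondrial steroid enzymes, of 1.33, Stra6, a retinol transporter, of 1.32, and Slc7a8, an amino acid transporter, of 1.31. All named higher genes except Stra6 were higher in the PS-MP library in each of the 7 granulosa-like clusters. Stra6 had a ratio of 0.961 (0.795 to 1.157) in cluster 9. Ratios ran from 1.32 to 1.74 for Slc38a1, 1.31 to 1.55 for Rgcc, 1.175 to 1.707 for Sdf2l1 and 1.13 to 1.80 for Pgbd5. The intervals of Slc38a1, Rgcc and Sdf2l1 lay above 1 in every cluster. In cluster 12 those of the other named higher genes included a ratio of 1, with 0.854 to 1.48 for Pgbd5. Pgbd5, Sh3bp5, Igfbp4 and Cyp11a1 were among the genes that led a sub-cluster of mostly PS-MP cells at resolution 0.8, and without that sub-cluster their ratios in granulosa-like cells were 1.40, 1.33, 2.04 and 1.334.

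Below Grem1, the named lower genes were Masp1, a protease of the lectin pathway, at 0.439 (0.425 to 0.452), Cyp19a1 at 0.488, Fmn1, a formin that nucleates actin filaments, at 0.543 (0.520 to 0.567), and Inhba at 0.552. Adamts5, a protease of the matrix proteoglycan versican, had a ratio of 0.594, Psd of 0.611, Ghr, the growth hormone receptor, of 0.624, Vcan, versican itself, of 0.645, and Nipal1 of 0.655. In cluster 6, which Inhba and Cyp19a1 lead, Grem1 stood at 660 and 148 CPM, Cyp19a1 at 578 and 215 CPM, and Inhba at 11511 and 5947 CPM in the control and PS-MP libraries. In cluster 3, led by mitotic genes, the order was the opposite for Inhba at 656 and 1189 CPM and for Cyp19a1 at 29.1 and 65.8 CPM. Cluster 9 also held dividing cells, with Top2a at 1524 CPM in the control library against 1100 CPM in cluster 3, and Inhba and Cyp19a1 helped lead it. Cluster 3 held 1638 control and 2392 PS-MP cells, and cluster 9 held 737 and 241. Ratios within cluster 3 therefore depend on how cells were split between these clusters and are not read as a rise in dividing cells. Inhba was also higher in the PS-MP library in cluster 5, with a ratio of 1.199 (1.125 to 1.279), as was Cyp19a1 in cluster 7, with 1.49 (1.25 to 1.78). The intervals included a ratio of 1 for Inhba in clusters 4 (0.983) and 7 (0.993) and for Cyp19a1 in clusters 4 (1.001), 5 (0.863) and 12 (0.694). In cluster 9 the ratios were 0.721 for Inhba and 0.859 for Cyp19a1, and in cluster 12 that of Inhba was 0.798. Grem1 had a ratio of 0.570 in cluster 3, 0.654 in cluster 4, 0.571 in cluster 5, 0.534 in cluster 7 and 0.408 in cluster 9, while in cluster 12 it stood at 3.71 and 4.06 CPM. In clusters 3, 4, 5 and 7 the ratios of Adamts5 ran from 0.593 to 0.645, those of Ghr from 0.545 to 0.657 and those of Nipal1 from 0.529 to 0.684, all with intervals below 1. Nipal1 was higher in the PS-MP library in cluster 6, with a ratio of 1.385 (1.136 to 1.688), and in cluster 9, with 2.62 (1.73 to 3.95).

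**Figure D3:**
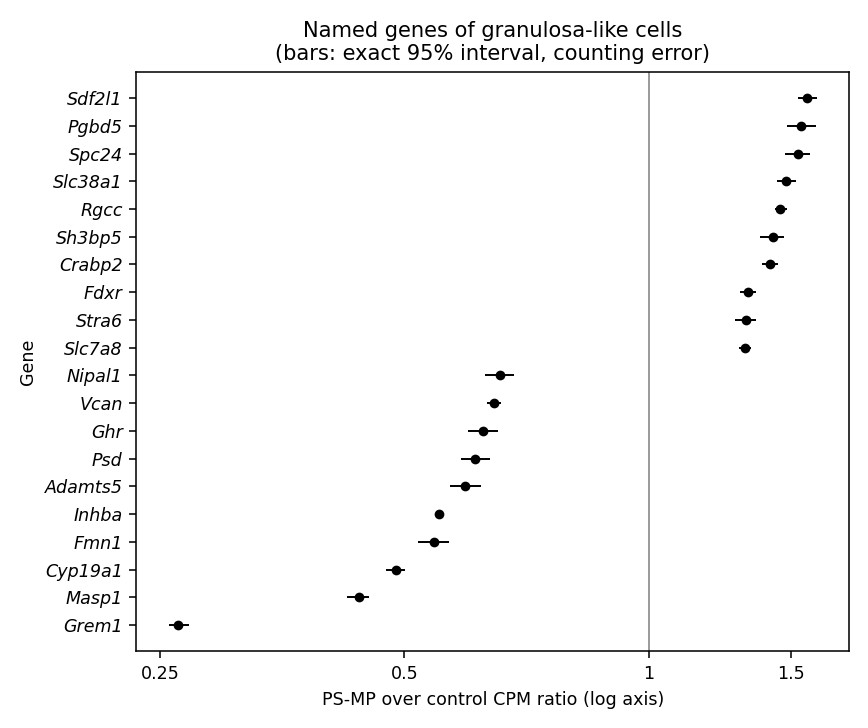
PS-MP over control CPM ratio (log axis) of the 20 named genes of granulosa-like cells; points are ratios and bars exact 95% intervals for counting error. Ratios run from 0.263 for Grem1 to 1.57 for Sdf2l1.

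Of the gene lists, the granulosa identity and follicle growth list had the lowest median in granulosa-like cells, at −0.14 on the log2 scale, below every random list. This median came to −0.071 (percentile 0.12) under the stricter cell filter and to −0.078 (percentile 0.08) with sub-clusters weighted alike. The list had 0 of 24 measured members at least 1.2-fold higher and 7 lower, among them Inhba, Nppc, which encodes the peptide that holds oocytes in meiotic arrest, at 0.680, Bmpr2 at 0.782 and Fshr, the FSH receptor, at 0.791. The TGF-beta and BMP signalling list had a median of −0.13 (percentile 0.03), with 1 member higher and 2 lower of 19; Tgfbr3 stood at 0.830 and Id2 at 1.21, and with sub-clusters weighted alike the median came to −0.05 (percentile 12.0), inside the central 95% of random lists. The unfolded protein response list had the highest median, 0.17 (percentile 100), with 5 of 21 members higher and 0 lower. These included Sdf2l1, Creld2 at 1.31, Manf at 1.29 and Hyou1 at 1.24, which act in protein folding in the endoplasmic reticulum. Glycolysis had a median of 0.14 (percentile 100, 3 higher and 0 lower of 16), with Pgk1 and Ldha both at 1.19, short of 1.2-fold. The glycolysis median came to 0.070 (percentile 99.4) with sub-clusters weighted alike. Cell cycle had a median of 0.13 (percentile 100, 2 higher and 0 lower of 29), with H2az1 at 1.218 and, short of 1.2-fold, Pcna and Mcm5 both at 1.18. This median came to 0.01 (percentile 85.7), also inside the central 95%, with sub-clusters weighted alike. Heat shock and proteostasis had a median of 0.12 (percentile 99.8), nuclear oxidative phosphorylation 0.08 (percentile 100) with 0 of 32 members past 1.2-fold, and immediate early genes, which tissue dissociation also induces, 0.08 (percentile 99.6). With cluster 17 counted as granulosa-like, the unfolded protein response median came to 0.04 (percentile 93.0) and that of TGF-beta and BMP signalling to −0.064 (percentile 22.9), both inside the central 95% of random lists. Granulosa identity then came to −0.32 and glycolysis to 0.30, and the medians of cell cycle (−0.10) and immediate early genes (−0.029) reversed.

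For the gene groups that the series title names, the list medians in granulosa-like cells were small. The formin Fmn1, with a ratio of 0.543 (0.520 to 0.567), is not a member of these fixed lists. All 37 measured members of the actin cytoskeleton list lay within 1.2-fold, and the list's percentile was 34.7; Ezr had a ratio of 1.14, Tmsb4x of 0.869 and Vcl of 0.839. Tubulin and microtubule genes had a median of 0.03 (percentile 74.4) with 1 lower of 19, Tuba1a standing at 0.829 and past 1.2-fold. Intermediate filament and nuclear lamina genes had a median of 0.06 (percentile 95.03) over 6 members. Gap and adherens junction genes had a median of −0.02 (percentile 27.2), with Fscn1, an actin-bundling protein, at 1.24 and Cdh2, N-cadherin, at 0.790. DNA methylation machinery had a median of −0.08 (percentile 6.27) with 1 of 17 lower, and Uhrf1 at 1.11. Histone methylation enzymes had a median of −0.05 (percentile 5.28) with all 40 members within 1.2-fold, Kdm6a standing at 0.847, and histone acetylation enzymes −0.05 (percentile 13.2) with all 21 within 1.2-fold. These medians lay inside the central 95% of random lists. With cluster 17 counted as granulosa-like, the actin cytoskeleton median was 0.071 (percentile 99.8), outside that range.

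Steroidogenesis had a median of 0.01 (percentile 51.2) with members on both sides: Cyp19a1 at 0.488, and Cyp11a1 at 1.454 (1.412 to 1.499), or 1.334 (1.293 to 1.376) without the sub-cluster led by Kcnk3, Fdxr at 1.33 and Hsd17b1 at 1.203. Cyp11a1 in granulosa-like PS-MP cells was 1.52% of its level in cluster 17, and Tinagl1 and Cemip, which lead that cluster, stood there at 1.69% and 0.91%. Ovulation and luteinisation had a median of −0.04 (percentile 22.8), with Prlr at 0.587, Vcan at 0.645 and Cebpb at 1.202. Extracellular matrix had a median of −0.08 (percentile 2.98) with Ccn2 at 0.812, and lipid uptake and storage −0.08 (percentile 4.48) with Cd36 at 0.817. Cholesterol synthesis had a median of 0.04 (percentile 95.9), antioxidant and metal response −0.01 with Mt1 at 1.24 and Gsta4 at 0.695, and apoptosis 0.02 (percentile 90.8) with all 20 members within 1.2-fold. The mitochondrial genome had a median of −0.01, the Hippo pathway −0.03, and lysosome and autophagy −0.01. Inflammation had a median of 0.08 over 5 members with Cxcl1 at 1.25, the interferon response 0.02 over 5, antigen presentation 0.07 over 3, and the aryl hydrocarbon receptor list −0.06 over 4. Angiogenesis had 2 measured members, Vegfa and Vegfb, both at 1.05.

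**Figure D4:**
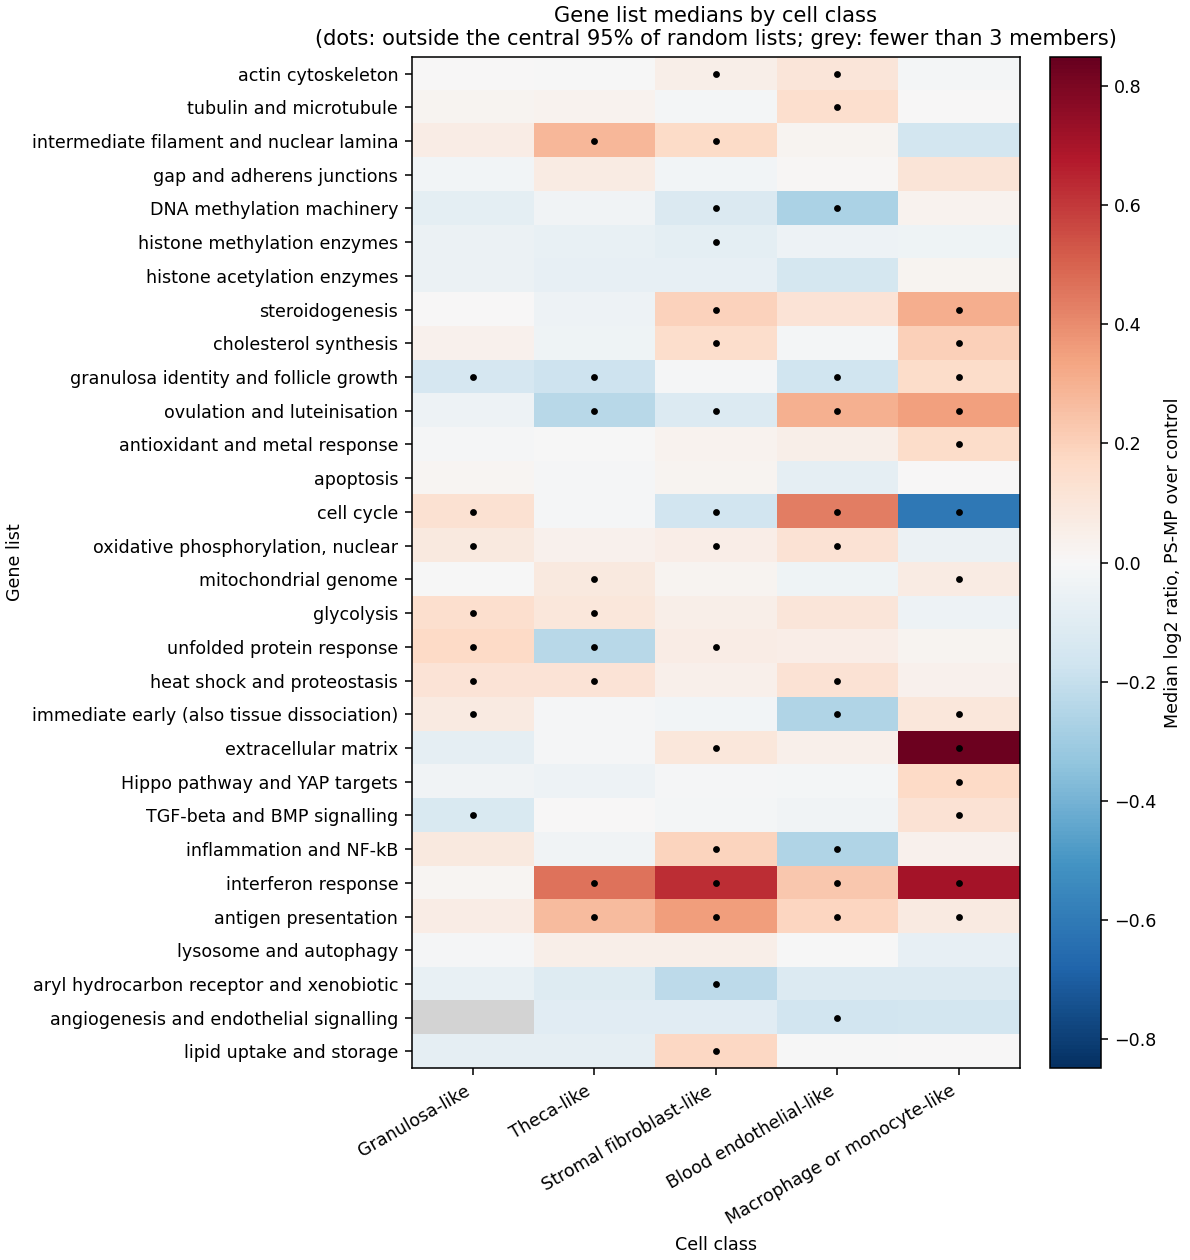
Median log2 ratio (colour, PS-MP over control) of 30 gene lists in 5 cell classes; dots mark medians outside the central 95% of random lists, and grey marks a list with 2 measured members. The interferon response median was 0.02 in granulosa-like, 0.46 in theca-like, 0.63 in stromal fibroblast-like, 0.23 in blood endothelial-like and 0.70 in macrophage or monocyte-like cells.

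Granulosa-like cells formed 11 sub-clusters. Sub-cluster 6, led by the mitotic genes Ube2c, Ccnb1, Hmmr and Plk1, held 9.78% of control granulosa-like cells (9.21 to 10.4) and 14.3% of PS-MP ones (13.5 to 15.0); the ratios of its leading genes in the whole class ran from 0.979 to 1.14. Sub-cluster 7, led by E2f8, Esco2, Kif11 and Top2a among others, held 8.20% (7.67 to 8.75) and 7.02% (6.50 to 7.56); Grem1, with a ratio of 0.263, was also among its leading genes, so these shares are given as values and are not read as a difference in size. Of the clusters of all cells, cluster 3, led by mitotic genes, held 16.0% of control and 26.2% of PS-MP granulosa-like cells, and cluster 9, with Top2a at 1524 and 1496 CPM, held 7.20% and 2.64%. Inhba, Cyp19a1 and Grem1, whose levels differ between the libraries, were among the leading genes of cluster 9, so its size is not independent of them. Top2a, a topoisomerase of dividing cells, had a UMI in 44.4% and 49.6% of granulosa-like cells as deposited and in 32.9% and 38.1% of cells thinned to equal depth. For Mki67, another gene of dividing cells, the thinned shares were nearer to each other, at 23.1% (22.3 to 24.0) and 24.3% (23.4 to 25.2), and their intervals overlapped. In macrophage or monocyte-like cells the thinned shares were 17.8% and 15.6% for Top2a and 19.1% and 14.1% for Mki67. Sub-cluster 0, led by Igfbp5, Scube3 and Amh, held 11.3% and 10.7%, sub-cluster 1, led by Ntng1 and Lrrtm3, 23.86% and 25.02%, and sub-cluster 9, led by Rbfox1 and Kcnq5, 1.01% and 0.779%. The remaining sub-clusters were not compared in size, because genes leading them differed 1.5-fold between the libraries or because stromal (Col1a1) or immune (Cd74) genes led them.

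RNA from granulosa-like cells was present in other cells. Inha, a granulosa gene, had a UMI in 99.8% of control and 99.9% of PS-MP granulosa-like cells, and in 71.3% and 73.6% of macrophage or monocyte-like cells, whose median depths were 6829 and 5642 UMIs. Thinned to equal depth, the shares in macrophage or monocyte-like cells were 51.9% and 60.5%. The Inha level in those cells was 15.3% and 14.8% of the granulosa level, and in stromal fibroblast-like cells 3.53% and 3.65%. In control macrophage or monocyte-like cells Inhbb, Fst and Hsd17b1, further granulosa genes, stood at 15.3%, 14.8% and 15.5% of their granulosa levels, close to the fraction of Inha. In the PS-MP library these fractions were further apart, at 12.2% for Inhbb, 18.6% for Fst and 13.85% for Hsd17b1, and Nr5a2 stood at 21.4%. Named genes that stand far higher in granulosa-like cells, such as Inhba in endothelial-like and macrophage-like cells, are read against that background.

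In theca-like cells, which make androgens around the follicle, 72 of 7110 genes were at least 1.5-fold higher and 75 lower in the PS-MP library; thinned cells gave 143 and 173. The highest named gene was Trf, transferrin, with 27 control and 323 PS-MP counts and a ratio of 14.0 (9.42 to 21.5), followed by Rrad at 3.77 and Cxcl10, a chemokine induced by interferon, at 2.56. The lowest were Saa3, an acute-phase protein, at 0.209 (0.161 to 0.269), Serpina3a at 0.294 and Cxcl12, a chemokine, at 0.440. The interferon response list had 8 of 10 measured members higher and 0 lower, with Ifitm3 at 1.996. The unfolded protein response list stood the other way from granulosa-like cells, at −0.24 (percentile 0) with 8 of 20 members lower, among them Pdia4 at 0.759 and Calr at 0.828. Ovulation and luteinisation had a median of −0.24 (percentile 0.02), with Lhcgr at 0.708, and Cyp17a1, the enzyme of androgen synthesis, had a ratio of 0.739 (0.722 to 0.757). Extracellular matrix members went both ways, 13 higher and 7 lower of 33, with Mmp2 at 1.85 and Col6a3 at 0.686.

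In stromal fibroblast-like cells, 61 of 7145 genes were higher and 15 lower. The higher genes numbered 40 with sub-clusters weighted alike, and the lower genes 9 with doublets kept and 31 in thinned cells. Spp1, osteopontin, was highest at 7.57 (6.60 to 8.72), with 13.9 and 106 CPM; it was also abundant in cluster 17, and its stromal level was 12.5% of the level there, against 2.96% for Tinagl1 and 2.52% for Cemip. Car3, a carbonic anhydrase, followed at 3.76, and Ifi27l2a, an interferon-induced gene, at 2.12. The lowest named genes were Penk, the enkephalin precursor, at 0.459, Rasd1 at 0.645 and Ccn2 at 0.653. The interferon response list had 9 of 11 members higher and 0 lower, with Gbp2 at 1.94. Inflammation had a median of 0.19 (percentile 100) with Cxcl10 at 1.59 and Ccl2 at 1.30, and antigen presentation 0.35 with H2-K1 at 1.31. Extracellular matrix had a median of 0.10 with Col18a1 at 2.07, Lox at 1.93 and Timp1 at 1.85. Cell cycle had a median of −0.16 (percentile 0), with 8 of 28 members lower and Mki67 at 0.765.

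In macrophage or monocyte-like cells, 258 of 7038 genes were higher and 118 lower. These numbers were 159 and 78 with doublets kept, the higher genes numbered 127 with sub-clusters weighted alike, and the lower genes 206 in thinned cells. Ly6c2, a marker of inflammatory monocytes, was highest at 3.92 (3.41 to 4.52), then Retnla at 3.03 and Ifi47, an interferon-induced GTPase, at 2.59. The lowest were Ighg2b, an immunoglobulin heavy chain, with 539 control and 5 PS-MP counts, Arg1, arginase, at 0.309 (0.276 to 0.345), and Inhba at 0.427. The Ighg2b order turned when doublets were kept and when sub-clusters were weighted alike. The interferon response list had 14 of 16 members higher and 0 lower, with Oasl2 at 2.18 and Ifitm3 at 1.60. Cell cycle had a median of −0.61 (percentile 0), with 22 of 26 members lower and Birc5 at 0.572. Extracellular matrix had a median of 0.83 with 19 of 25 members higher; Col1a1 stood at 33.4 and 115 CPM, which was 0.68% and 1.93% of its stromal level, and Col4a2 at 24.5 and 87.7 CPM. The steroidogenesis median was 0.31, with Cyp11a1 at 162 and 498 CPM, 7.14% of the cluster 17 level in the PS-MP library, where Tinagl1 stood at 5.51% of its own level there. Cemip, at 5.17 and 52.1 CPM, and Fdx1, at 98.6 and 356 CPM, reached 5.06% and 5.94% of their cluster 17 levels in the PS-MP library. The 100 genes leading cluster 17 had a median log2 ratio of 1.25 in macrophage or monocyte-like cells. The 258 higher genes and the steroidogenesis median may therefore include RNA carried over from cluster 17, and how much was not tested.

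In blood endothelial-like cells, 159 of 7322 genes were higher and 235 lower, from 352 and 315 cells; thinned cells gave 312 and 468. Kcne3, a potassium channel subunit, was highest at 2.52 (1.86 to 3.44), then Apln, a peptide of endothelial tip cells, at 2.36 (1.98 to 2.83). The lowest were Ccl21a, a lymphatic chemokine, at 0.227, Gadd45b at 0.451 and Inhba at 0.456. Cells with at least 3 lymphatic markers were 13 of 352 control cells (3.69%, 1.98 to 6.23) and 5 of 315 PS-MP cells (1.59%, 0.517 to 3.67). Cell cycle had a median of 0.44 (percentile 100), with 22 of 28 members higher and 0 lower, and Mcm5 at 1.81. The interferon response list had a median of 0.23 (percentile 99.96), with 5 of 13 members higher and 2 lower. DNA methylation machinery had a median of −0.27 (percentile 0.06), with 9 of 18 members lower, among them Dnmt3a at 0.744. Immediate early genes had a median of −0.26 (percentile 0), with Atf3 at 0.712, and inflammation −0.26, with members both ways: Cxcl2 at 0.481, Vcam1 at 0.512 and Cxcl10 at 1.62. Actin cytoskeleton had a median of 0.10 (percentile 99.9), with 1 of 42 members past 1.2-fold, Myl9 at 1.38.

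**Figure D5:**
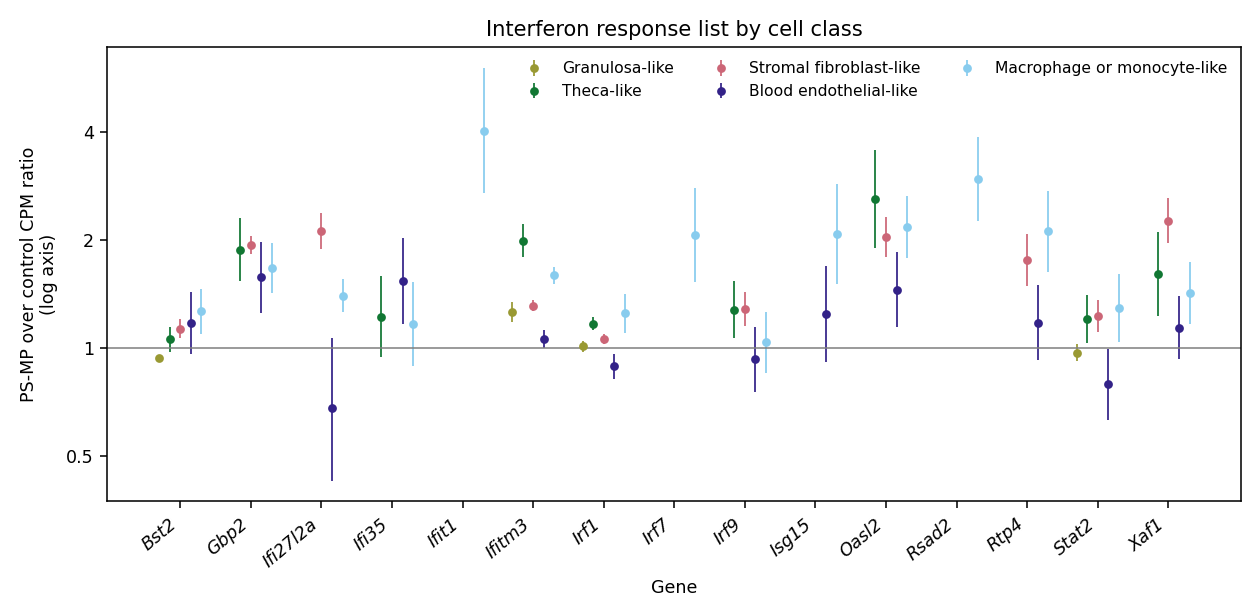
PS-MP over control CPM ratio (log axis) of 15 interferon response genes in 5 cell classes; points are ratios and bars exact 95% intervals for counting error. Oasl2 had ratios of 2.60 in theca-like, 2.04 in stromal fibroblast-like and 2.18 in macrophage or monocyte-like cells.

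Luteal-like cells and all cells summed reflected cluster 17. In the luteal-like class, 997 of 7352 genes were higher and 738 lower, with Spp1 at 88.3 (63.7 to 126), Tinagl1 at 26.0 and Adamts1 at 23.3 highest and Tcim at 0.050, Prrx2 at 0.058 and Nrep at 0.060 lowest. Of this class, 232 of 236 control cells lay in cluster 2 and 1893 of 2027 PS-MP cells in cluster 17, so these ratios mostly compare different clusters. Within cluster 2 alone, with 232 and 134 cells, 345 genes were higher and 409 lower. Summed over all cells, 155 of 7663 genes were higher and 114 lower; without cluster 17 the numbers were 8 and 84. Edn2, endothelin 2, stood at 1.69 and 54.8 CPM over all cells.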

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

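The alternatives that treated cluster 17, cluster 2, the mixed sub-clusters or the sub-cluster led by Kcnk3 in another way were chosen after seeing the data; the others were planned. No paired analysis was possible because both samples are single libraries of different mice. Across the alternatives, 87 counts of genes, 332 list medians, 290 named gene values and 10 shares stayed within 1.5 times the count or within their limits, and 25, 23, 78 and 4 moved beyond them. With doublets kept, the granulosa-like shares were 69.3% and 61.6%, macrophage or monocyte-like genes numbered 159 higher and 78 lower, stromal fibroblast-like genes 9 lower, and the Ighg2b log2 ratio in macrophage or monocyte-like cells reversed to 2.43; the cause was not tested. With the stricter cell filter, the granulosa identity median was −0.071; the cause was not tested. Thinned cells gave 312 higher and 468 lower blood endothelial-like genes, 8 higher granulosa-like genes, 206 lower macrophage or monocyte-like genes, 31 lower stromal fibroblast-like genes, 143 higher and 173 lower theca-like genes, and a cell cycle median of 0.18 in granulosa-like cells, as did the mean of cells (0.18). Thinning leaves fewer counts, and the simulated blood endothelial-like cells already gave 86 unchanged genes past the ratio from counting error. Sub-clusters weighted alike gave 8 higher granulosa-like genes, 347 higher and 441 lower luteal-like genes, 127 higher macrophage or monocyte-like genes and 40 higher stromal fibroblast-like genes. In granulosa-like cells that weighting gave medians of 0.014 for cell cycle, 0.070 for glycolysis, 0.003 for extracellular matrix, −0.05 for TGF-beta and BMP signalling and −0.078 for granulosa identity, and it reversed the Ighg2b log2 ratio in macrophage or monocyte-like cells to 2.94; the cause was not tested. By construction, a floor of 5 CPM gave 19 higher and 113 lower granulosa-like genes, a floor of 50 CPM 14 lower, and a ratio of 2 gave 1 higher and 8 lower. With cluster 17 counted as granulosa-like, the share was 76.4%, and 254 genes were higher and 98 lower. The medians then reversed to −0.10 for cell cycle and −0.029 for immediate early genes. They moved to 1.01 for ovulation and luteinisation, 0.37 for antigen presentation, 0.36 for steroidogenesis, 0.30 for glycolysis, 0.28 for cholesterol synthesis, 0.18 for extracellular matrix, 0.10 for lysosome, 0.086 for antioxidant response, 0.071 for actin, 0.04 for unfolded protein response, −0.063 for tubulin, −0.064 for TGF-beta and BMP signalling, −0.12 for junctions and −0.32 for granulosa identity. These moves come from the added cells of 1 library. Without cluster 17 the granulosa-like share of the PS-MP library was 72.8%, and 8 genes were higher over all cells. Without the sub-cluster led by Kcnk3, the cell cycle median in granulosa-like cells was 0.194; the cause was not tested. Cluster 2 alone gave 345 higher and 409 lower luteal-like genes. Granulosa-like sub-clusters numbered 6 at resolution 0.3 and 13 at 0.8, and the sub-cluster led by mitotic genes held 18.3% and 22.2% at the former and 10.2% and 13.9% at the latter. Depth limits the smaller classes: blood endothelial-like cells rested on 2985674 and 2261888 counts, and granulosa-like cells on 110025671 and 88448437.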

Other observations

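The tests of a technical shift and of the stage of the cycle for cluster 17, and those of the mix of sub-clusters and of library depth and the count of genes lower in other clusters for the lower granulosa-like genes, were chosen after the results were seen.

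Set against granulosa-like cells of the same PS-MP library, cluster 17 was higher for 13 of 14 ovulation and luteinisation genes, 19 of 24 extracellular matrix genes and 13 of 19 steroidogenesis genes. Its cell cycle list was lower in all 29 measured members, with a median log2 ratio of −1.83, and its granulosa identity list in 22 of 24, with −2.19. The ovulation, steroidogenesis and granulosa identity lists share genes with the luteal or granulosa markers used for naming, Lhcgr, Akr1c18, Inha and Fshr among them. Their values are thus no independent evidence of what the cluster is. Inha stood at 1425 CPM in cluster 17 and 10229 CPM in granulosa-like cells. In blood endothelial-like cells, the angiogenesis list had a median of −0.16 (percentile 0.52) with members both ways: Apln stood at 2.36 and Aplnr, its receptor, at 1.37, while Hey1, a Notch target, stood at 0.638 and Vegfc at 0.724. In stromal fibroblast-like cells, the aryl hydrocarbon receptor list had a median of −0.22 over 4 members, with Cyp1b1 at 0.692, and the steroidogenesis list 0.20, with Cyp11a1 at 1.93% of its cluster 17 level. In macrophage or monocyte-like cells, the antioxidant list had a median of 0.16 (percentile 100), with 10 of 27 members higher and 0 lower. Clustered at resolution 0.8, granulosa-like cells held a sub-cluster led by Kcnk3, Igfbp4, Mrap and Pgbd5, with Cyp11a1 and Sh3bp5 also among its leading genes, of 85 control cells (0.830%) and 657 PS-MP cells (7.21%). It was seen after the fact, and genes that lead it differ between the libraries, so its shares are given as values.

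Cluster 17 held 1893 PS-MP cells and 4 control cells. Doublets are argued against, since its median doublet score was 0.0161 and that of all kept cells 0.0265. For a technical shift of the whole PS-MP library, the 100 genes leading cluster 17 were compared between the libraries. Their median log2 ratio was 0.27 in granulosa-like cells, 0.14 in theca-like, 0.42 in blood endothelial-like and 0.48 in stromal fibroblast-like cells. It was 1.25 in macrophage or monocyte-like cells and 1.46 over all cells, which include cluster 17. The genes were picked as highest in cluster 17 against all other cells, which favours small differences elsewhere. These values therefore cannot decide on a technical shift. Stage of the cycle and exposure cannot be told apart, because the labels give no cycle stage and no cell can be assigned to a mouse; the ovulation and luteinisation list, higher in cluster 17 by a median of 3.17, shares Lhcgr, Ptgfr, Prlr and Parm1 with the markers that named the cluster and would be higher in either case.

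Interferon response genes were higher in theca-like, stromal fibroblast-like and macrophage or monocyte-like cells of the PS-MP library. Another mix of the sub-clusters found at resolution 0.5 is argued against for theca-like, stromal fibroblast-like and macrophage or monocyte-like cells. With sub-clusters weighted alike, the lowest of their medians was 0.42, above the random lists. Sub-clusters with fewer than 20 cells in a library were left out of the weighting, so a change in those is not covered, nor is a finer change of mix. RNA carried over from macrophage-like cells is argued against for theca-like and stromal fibroblast-like cells, where the median log2 ratios of macrophage markers were −0.62 and −0.61, over 2 markers in each. For animals or handling of the library against exposure, the design holds 1 library per group, so these cannot be told apart, and an infection or a difference in tissue handling could also give this pattern.

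The 10 named lower genes of granulosa-like cells had a median log2 ratio of −0.80. Another mix of the sub-clusters found at resolution 0.5 is argued against by a median of −0.80 with those sub-clusters weighted alike. A finer change of mix within them is not covered by this weighting. Thinned cells gave −0.81, which cannot decide on library depth. The CPM values were already scaled to each class's total, so thinning was bound to leave the ratios nearly unchanged. For a loss limited to the clusters led by Inhba and Cyp19a1, the planned test gave a median of −0.36 outside clusters 6 and 9 beside −0.94 within them. The value outside lay between the bounds of −0.2 and −0.5 and decided nothing. Counted afterwards, 6 genes (Grem1, Fmn1, Adamts5, Ghr, Vcan and Nipal1) had intervals below a ratio of 1 in at least 3 of the 5 other clusters. Their lower values were thus not limited to clusters 6 and 9. This count draws no conclusion on a cause, because the genes were picked as the lowest over the whole class. Ghr and Nipal1 stood at only 11.1 and 9.03 CPM in control cells of cluster 6, so lower values elsewhere were needed for them to be picked. For Masp1, Cyp19a1, Inhba and Psd, with a median of 0.56 outside and −1.05 within, such a limited loss stays open, because these genes were picked by their values outside clusters 6 and 9. The exposure, which the design names, and the stage of the follicles in the mice pooled remain open as untested explanations.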
